A study of Arabidopsis thaliana with 36 samples.

How the data were processed

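The samples were the aerial parts of 10-day-old Arabidopsis thaliana seedlings (Columbia, wild type), grown on agar with sucrose under 16 h of light and 8 h of dark. Per the labels' protocols, seedlings were harvested at Zeitgeber time (ZT, hours after lights on) 0, 6, 12 and 18, and RNA was separated by its association with ribosomes into a non-polysomal, a small polysomal and a large polysomal fraction. Each of the 12 groups (4 times, 3 fractions) had 3 replicates, 36 arrays in all. The series' design also names seedlings overexpressing CCA1, which were not analysed here. Whether replicates of a time came from independently grown plants is not stated, so p-values measure the spread between these samples.

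Per the labels' protocols, complementary DNA was primed with oligo(dT) and biotinylated RNA was hybridised to Affymetrix arrays. The deposited values are log2 expression summaries per probe set, made by the authors with GCRMA using affy 1.42.3 in R 3.1, per the submitters' processing notes. The values in the table were distributed almost alike on every array, so each value is relative to the average mRNA of its array. Differences in total mRNA between fractions or times are therefore not seen. Arrays carry no read depth, and their number limits the precision.

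The table held 22810 probe sets, of which 64 were control probe sets. The probe table paired 13513 probe sets with 1 gene and 503 with several, and it did not list 8730 others, which are unnamed here. Gene names were updated through a gene table of assembly TAIR10.1 (GCF_000001735.4), where 6823 of the 6846 tested genes were matched; genes with no symbol there are given by their AGI code. A gene was tested when a single-gene probe set had a mean of at least 4 (log2) over the 36 arrays, using the brightest probe set of each gene. This left out 6510 of 13356 genes.

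Ribosome loading was taken as the large polysomal minus the non-polysomal value of the same time and replicate number. The transcript level was the mean of the 3 fractions of each extract (12 extracts, a time and a replicate number each). It is a stand-in for the total transcript level, since each fraction counts alike whatever its share of the RNA. Fractions were compared in a limma fit of all 36 arrays with 12 groups (limma 3.58.1, R 4.3.3), and levels in a limma fit of the 12 extracts. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. ZT6 against ZT18 and ZT12 against ZT0 were compared because these pairs lie 12 h apart and share no arrays. A moderated F test over the 4 times asked whether a gene's loading or level differed at any time. Deviations from the group means were correlated between fractions of one extract in all 36 fraction pairs (r 0.13 to 0.68), so the replicate numbers pair the fractions. Loading and fraction differences were also fitted with the extract as a replicate block. Where the block is not named, their calls and SEs are those of the fit without it, which does not use this pairing.

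Gene lists were tested with limma's camera (preset correlation 0.01), adjusted over the lists within each contrast, for lists of at least 5 tested members; camera with an estimated correlation and limma's fry were run beside it. Of the calls made with the preset correlation, none held with an estimated correlation in the fits without the extract block, and with the block 1 did. Written before the data were examined were lists for the core clock and clock-linked regulators (2 of 29 genes tested), light-harvesting proteins (3 of 21), nuclear-encoded photosystem and electron transport subunits (5 of 31), Calvin-Benson cycle enzymes (3 of 19), photorespiration enzymes (4 of 17), chlorophyll synthesis enzymes (4 of 16), starch breakdown (2 of 16), sugar-starvation-induced genes (1 of 12), phenylpropanoid and flavonoid synthesis (2 of 15), cold-regulated genes (3 of 13), heat shock proteins (1 of 13), genes with conserved-peptide upstream open reading frames (9 of 18), translation factors (1 of 24), proteasome subunits (3 of 29), cell division and DNA replication (2 of 23) and root markers (1 of 11). Lists for nitrate assimilation and for PIF and shade growth genes had 0 tested members. Lists by product text were not made, since the tables hold none. In their place, lists by AGI code of cytosolic ribosomal proteins (97 tested), plastid ribosomal proteins (10) and the mitochondrial respiratory chain (9), and a list joining the 5 photosynthesis lists (19), were written after the probe table was seen and before any test. Plastid-encoded (62) and mitochondrion-encoded genes (6) were to be taken by their AGI codes, which the tables do not hold for them, and were taken instead by chromosome in the gene table and by mitochondrial gene names.

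Genes named in the text follow a rule written before the data were examined. For each contrast, these are the 5 called genes with the largest change in each direction among those that moved the same way in every pair of values, for the F test of loading the 5 with the largest range, and from each list up to 4 called members with the largest change. Where no member of a list passed, up to 2 are given as values.

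The fits were tested on simulated data made from the spread of these arrays, with 6846 genes. Noise was drawn independently for each gene, so the shares and false calls do not cover swings shared by many genes. For large against non-polysomal RNA, 70.1% of genes changed by a log2 of 0.5 and 95.5% of those changed by 1 were recovered. For loading at ZT6 against ZT18 the shares were 2.99% at 0.5, 34.3% at 1 and 90.9% at 2, and for the level 32.8%, 83.6% and 98.5%. Among 6246 unchanged genes, false calls were 5, 1 and 11 in these 3 comparisons.

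Alternatives tried were no filter and a mean of at least 6, median centring, cyclic loess, other probe set choices, a trended robust variance, array weights, replicate blocks, both polysomal fractions together against non-polysomal RNA, and leaving out each extract and each replicate number. After the data were seen, leaving out ZT18 replicates 2 and 3 (high organelle signal), leaving out organelle-encoded genes, the overlap of loading and level without genes near the lower end of the scale, and median centring for the list tests were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.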

Results

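Messenger RNA was measured on 36 arrays in the aerial parts of wild-type Arabidopsis seedlings, at 4 times of a day with 16 h of light, in RNA free of polysomes and in RNA bound to small or to large polysomes (few or many ribosomes per mRNA). There were 3 replicates of each time and fraction. Of 13356 genes with a probe set of their own, 6846 were bright enough to test. Replicate arrays of a group correlated at 0.934 or more. ZT0, ZT6 and ZT12 fell in the light period, with ZT0 at lights on, and ZT18 in the dark.

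The comparison of large polysomal with non-polysomal RNA asked which transcripts lay in large rather than no polysomes. Transcript lengths were not at hand, so a bias by length in this difference was not tested and stays open for each gene and list below. Transcripts of the cold-regulated genes COR47 (AT1G20440), a dehydrin, COR15B (AT2G42530) and COR15A (AT2G42540), which protect chloroplast membranes, were higher in large polysomes by a log2 difference of 2.54 ± 0.12, 2.1 ± 0.12 and 1.09 ± 0.18 (SE, 12 extracts). These were the 3 members of their list that were tested. All 5 tested nuclear genes for photosystem and electron transport subunits were also higher there. Among them were PSBY (AT1G67740) by 1.66 ± 0.09, ATPC1 (AT4G04640), a subunit of the chloroplast ATP synthase, by 1.04 ± 0.11, PSBW (AT2G30570) by 0.55 ± 0.09 and PSAN (AT5G64040) by 0.40 ± 0.08. Transcripts of cytosolic ribosomal proteins leaned to non-polysomal RNA: 59 of 97 were lower in large polysomes, 18 were higher and 20 did not pass, with a median of -0.36. Their extremes were AT2G40010 at -3.40 ± 0.17, with its lowest group mean at 2.40 near the lower end of the scale, AT3G22230 at -1.77 ± 0.13, AT4G34555 at 1.80 ± 0.12 and AT4G30800 at 1.75 ± 0.15.

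Other lists were split or small. Of 4 chlorophyll synthesis enzymes, HEMB1 (AT1G69740) was higher in large polysomes by 2.35 ± 0.13, GSA1 (AT5G63570) by 0.81 ± 0.17 and PORB (AT4G27440), which reduces protochlorophyllide, by 0.78 ± 0.13. CHLM (AT4G25080) was lower, at -0.84 ± 0.09. Of 3 genes for the antenna protein CP29, LHCB4.3 (AT2G40100) was higher by 1.13 ± 0.15, and LHCB4.2 (AT3G08940) at -0.47 ± 0.11 and LHCB4.1 (AT5G01530) at -0.34 ± 0.07 were lower. Joined with the Calvin-Benson and photorespiration enzymes, 11 of the 19 photosynthesis genes tested were higher and 4 lower (13 and 4 with the extract as a replicate block). Of the genes with conserved-peptide upstream open reading frames, 6 of 9 were higher, among them AT5G15950 by 0.94 ± 0.18, PMEAMT (AT1G48600) by 0.85 ± 0.10 and SAMDC (AT3G02470), an enzyme of polyamine synthesis, by 0.76 ± 0.14. Another 2 were lower, among them BZIP53 (AT3G62420) at -0.75 ± 0.15. Of 10 plastid ribosomal proteins 5 were higher and 3 lower. Their extremes were AT1G64510 at 1.89 ± 0.14, AT5G24490 at 1.2 ± 0.11, AT1G29070 at -1.22 ± 0.11 and AT5G65220 at -1.22 ± 0.09. Of 9 nuclear genes of the mitochondrial chain 4 were higher and 1 lower. These included SDH1-1 (AT5G66760), of succinate dehydrogenase, at 1.75 ± 0.15, SDH2-1 (AT3G27380) at 0.93 ± 0.14, AT3G27240 at 0.51 ± 0.15 and AT1G51980 at -0.53 ± 0.15. The call of AT1G51980 ended without replicate 1 (-0.37, adjusted p 0.112 in limma). Higher in large polysomes were also the histone gene HTB1 (AT1G07790) by 1.65 ± 0.14, the replication gene PRL (AT4G02060) by 0.92 ± 0.13 and the initiation factor EIF4A-2 (AT1G54270) by 1.02 ± 0.12. So were the proteasome gene AT2G32730 by 1.49 ± 0.09, RPN12a (AT1G64520) by 0.34 ± 0.08 and PWD (AT5G26570), of starch breakdown, by 1.2 ± 0.13. Others were the photorespiration genes AT1G11860 by 0.80 ± 0.11 and HPR (AT1G68010) by 0.34 ± 0.09, GI (AT1G22770) by 0.91 ± 0.13, and PYK10 (AT3G09260), a glucosidase abundant in roots, by 1.17 ± 0.12. The value of GI averages in ZT0 and ZT18, where it lay at the lower end of the scale and its loading was not measured. The photorespiration gene AT1G32470 was lower, at -0.32 ± 0.07. The clock-linked gene AT5G52660 was higher by 0.29 ± 0.10 and AKINBETA1 (AT5G21170), of the SnRK1 kinase, by 0.30 ± 0.13. Both calls ended with median centring (adjusted p 0.054 and 0.130 in limma) and with cyclic loess (0.187 and 0.092), and that of AKINBETA1 without any of 7 single extracts (ZT0 replicates 2 and 3, ZT6 replicates 2 and 3, ZT12 replicate 2, and ZT18 replicates 2 and 3) and with no filter on dim genes (0.067). RCA (AT2G39730) at 0.27 ± 0.16, SBPASE (AT3G55800) at 0.09 ± 0.09, DFR (AT5G42800) at -0.57 ± 0.31, UGT78D1 (AT1G30530) at 0.03 ± 0.10 and the heat shock gene AT5G37670 at 0.10 ± 0.13 did not pass. With the extract as a replicate block RCA (adjusted p 0.022) and DFR (9.8e-06) did.

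Transcripts encoded in the organelles read lower in large polysomal than in non-polysomal RNA, relative to the average mRNA. Of 62 plastid-encoded genes 41 were lower there and 3 higher (median -1.46), with petG, of the cytochrome b6f complex, at -4.19 ± 0.55, rps16 at -3.44 ± 0.40, psaC at -3.02 ± 0.71 and psaJ, of photosystem I, at -2.89 ± 0.32. With the extract as a replicate block 51 were lower and 7 higher. Of the mitochondrion-encoded genes, 6 of 6 tested were lower, among them ccb452 at -2.68 ± 0.32, cox1 at -1.97 ± 0.37, nad4 at -1.91 ± 0.36 and ccb382 at -1.81 ± 0.30. Priming was with oligo(dT), and the added polyadenylated control transcripts were themselves lower in large than in non-polysomal RNA, by a mean of -1.88 ± 0.83 (SD, n = 12), in 12 of 12 extracts. The same difference for the hybridisation controls was -0.67 ± 0.18, again in 12 of 12. The medians of the plastid-encoded (-1.46) and mitochondrion-encoded genes (-1.86) did not go beyond that of the polyadenylated controls. For the lists as a whole, a low ribosome loading of organelle transcripts can therefore not be told apart from what lowered these controls. The named plastid genes, ccb452, cox1 and nad4 read below the mean of the controls, and ccb382 did not. They were named as the largest changes of their lists, and whether single genes went beyond the controls was not tested. The 3' minus 5' difference of the actin probe sets was higher in large polysomal than in non-polysomal RNA by 0.93 ± 0.34 in 12 of 12 extracts. For the GAPDH probe sets it was less even, at 0.23 ± 0.51 and below 0 in 3 of 12 extracts.

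Across the 6846 genes, 2753 were higher and 2570 lower in large polysomal RNA in limma's test, and 1046 and 1089 of these by a log2 difference over 1. The balance turned with median centring (2501 higher and 2789 lower) and with cyclic loess (2389 and 2931). The largest differences were AT1G64370 at 4.29 ± 0.14, AT4G34290 at 3.73 ± 0.13, AT5G45350 at 3.64 ± 0.13, AT1G04800 at 3.58 ± 0.12 and AT5G55660 at 3.17 ± 0.22. On the other side were AT5G55010 at -4.31 ± 0.18, petG, AT3G27340 at -4.03 ± 0.14, AT1G65370 at -4.03 ± 0.18 and AT5G21020 at -4.01 ± 0.28. Their adjusted p ran from 1.7e-21 (AT1G64370) to 4.3e-08 (petG), and AT5G55010 and petG had group means under 3, near the lower end of the scale. In 3391 genes (49.5%) large polysomal RNA lay on the same side of non-polysomal RNA in 12 of 12 extracts. Adjusted over the list alone, 18 cytosolic ribosomal protein genes were higher and 59 lower, 5 photosystem genes were higher, and 3 plastid-encoded genes were higher and 40 lower. As lists, cytosolic ribosomal proteins (adjusted p = 0.0035), plastid-encoded genes (adjusted p = 0.0032) and the photosystem subunits (adjusted p = 0.047) stood apart from the other genes in camera with its preset correlation; adjusted p = 0.687, 0.692 and 0.568 with an estimated correlation. The photosystem call also ended with the extract as a replicate block (adjusted p 0.066) and with median centring (0.058), and the mitochondrion-encoded list, at an adjusted p of 0.0501, passed with the block (0.0044), though not with the block and an estimated correlation (0.514). Cyclic loess shifted the median of all genes by -0.12, and the genes named above kept their direction relative to it.

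Between small polysomal and non-polysomal RNA, cytosolic ribosomal protein transcripts again leaned to the non-polysomal side, with 65 of 97 lower, 13 higher and a median of -0.53. The conserved-peptide open reading frame genes leaned the other way, with 7 of 9 higher in small polysomes and 0 lower. Between large and small polysomes, 37 ribosomal protein transcripts were higher in the large and 21 lower, 13 of the 19 photosynthesis genes were higher and 0 lower, and plastid-encoded transcripts were lower in 32 of 62 and higher in 0. In all, 2295 genes were higher and 1999 lower in small polysomal than in non-polysomal RNA, and 2056 higher and 2137 lower in large than in small polysomes (limma, adjusted p under 0.05). Median centring shifted the median of all genes by -0.13 between small polysomal and non-polysomal RNA and turned the balance of its calls to 1734 higher and 2531 lower (higher share 40.7%, against 53.4%), and cyclic loess turned it to 1989 and 2266. Between large and small polysomes median centring turned it to 2282 higher and 1955 lower.

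Transcript levels over the day, as the mean of the 3 fractions, asked which genes differed between times in these seedlings. The level of GI, a clock component, was 6.71 ± 0.21 (log2, SD, n = 3) at ZT6 and 5.42 ± 0.47 at ZT12, against 2.23 ± 0.03 at ZT0 and 2.25 ± 0.08 at ZT18. At midday against night (ZT6 against ZT18) it rose by 4.45 ± 0.20 (SE). The defence thionin gene THI2.2 (AT5G36910) rose by 5.92 ± 0.22, AT1G73480 by 5.47 ± 0.18, AT1G13650 by 5.22 ± 0.24 and the cytochrome P450 gene CYP71B26 (AT3G26290) by 5.13 ± 0.32. Lower at ZT6 were AT2G25990 at -4.51 ± 0.22, AT4G21870 at -4.28 ± 0.19, AT3G16530 at -3.75 ± 0.38, AT4G12500 at -3.68 ± 0.86 and AT4G12490 at -3.64 ± 1.02 (adjusted p 0.013; 0.078 with no filter on dim genes). DFR, an enzyme of anthocyanin synthesis, was at 8.05 ± 0.39 at ZT18 and at 4.79 ± 0.51 at ZT6, a change of -3.27 ± 0.53. UGT78D1, of flavonol synthesis, changed by -0.65 ± 0.15.

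Of the photosynthesis genes 10 of 19 were higher at ZT6 than at ZT18 and 3 lower (as a list, adjusted p = 0.010 in camera with its preset correlation, 0.689 with an estimated correlation, and 0.0506 with cyclic loess). The 5 photosystem and electron transport genes all rose, PSBY by 1.24 ± 0.13, ATPC1 by 0.97 ± 0.17, PSAN by 0.92 ± 0.15 and PSBW by 0.86 ± 0.13. So did LHCB4.2 by 1.96 ± 0.15, LHCB4.1 by 0.57 ± 0.12, PORB by 1.13 ± 0.20, HEMB1 by 0.60 ± 0.20 and CHLM by 0.43 ± 0.13. LHCB4.3 fell by 1.94 ± 0.23, AT1G32470 by 0.38 ± 0.12 and SBPASE by 0.38 ± 0.14. Of the plastid ribosomal proteins 6 of 10 rose and 0 fell. Among those that rose were AT5G24490 by 1.02 ± 0.18, AT2G43030 by 0.84 ± 0.16, AT3G13120 by 0.71 ± 0.21 and AT4G17560 by 0.61 ± 0.17. COR15A rose by 3.16 ± 0.30, COR15B by 1.71 ± 0.17, COR47 by 0.83 ± 0.17, the starch gene DPE1 (AT5G64860) by 0.90 ± 0.17, AT5G52660 by 1.16 ± 0.16, PYK10 by 0.96 ± 0.17 and AT5G37670 by 0.57 ± 0.18. So did the proteasome genes AT5G23540 by 0.62 ± 0.17 and RPN12a by 0.47 ± 0.12, and the mitochondrial chain genes AT5G40810 by 0.67 ± 0.15 and AT5G47030 by 0.37 ± 0.14. Of the 9 conserved-peptide genes 3 rose and 3 fell, among them AT5G50010 by 1.75 ± 0.17, AT1G73600 by 1.63 ± 0.19, AT5G15950 by 0.97 ± 0.27 and bZIP44 (AT1G75390) at -1.30 ± 0.19. Of the 97 cytosolic ribosomal protein genes 4 rose and 9 fell. Their median was -0.08 and the list did not pass camera with its preset correlation (adjusted p = 0.123), but with cyclic loess the median was -0.25 and the adjusted p 0.0055. With an estimated correlation, without the loess, it was 0.699. Those that fell included AT5G67510 at -0.85 ± 0.16, AT3G02190 at -0.80 ± 0.21, AT1G15250 at -0.66 ± 0.15 and AT1G74270 at -0.63 ± 0.14. AKINBETA1 at -0.35 ± 0.21, EIF4A-2 at -0.13 ± 0.20, PRL at 0.12 ± 0.20 and HTB1 at 0.00 ± 0.22 did not pass. Of the organelle genes 4 passed, rps18 at -1.84 ± 0.54, ndhC at -0.75 ± 0.28, ccb452 at -1.49 ± 0.53 and nad1 at -0.97 ± 0.28. Without ZT18 replicates 2 and 3, whose organelle signal was high, these changes were -0.38, -0.13, -0.36 and -0.70. The plastid-encoded median was -0.86, and the mean signal of the plastid genes in non-polysomal RNA at ZT18 varied between replicates (9.97 ± 1.68, SD, n = 3). The added polyadenylated controls were also lower at ZT6 than at ZT18, at 5.29 ± 0.35 (log2, SD, n = 3) against 7.06 ± 1.12 in non-polysomal, 5.11 ± 0.19 against 6.16 ± 0.79 in small polysomal and 4.12 ± 0.13 against 4.74 ± 0.31 in large polysomal RNA. Without 1 of the ZT6 or ZT18 extracts, the calls of HEMB1, CHLM, SBPASE, AT1G32470, AT3G13120, AT4G17560, AT5G37670, AT5G23540, AT5G47030, AT4G12490 and these 4 organelle genes ended in at least 1 case, and those of HEMB1, CHLM and AT5G47030 ended with cyclic loess (adjusted p 0.055, 0.130 and 0.176 in limma). Those of SBPASE and ndhC ended with median centring (0.062 and 0.055). With no filter on dim genes those of HEMB1, AT5G15950, AT5G37670, AT3G13120 and the 4 organelle genes ended (0.058 to 0.152), and a trended robust variance ended those of AT4G12490, rps18, ndhC and ccb452 (0.054 to 0.099). Levels from summed values ended those of CHLM and AT5G47030 (0.061 and 0.057). Leaving out a whole replicate number also ended the calls of AT5G15950 (0.081 without replicate 1) and RPN12a (0.056 and 0.085 without replicates 2 and 3). Without replicate 3 those of AT3G02190 (a change of -0.48, 0.098), AT1G74270 (-0.57, 0.058) and AT5G40810 (0.63, 0.059) ended.

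In total 1393 genes were higher and 1203 lower at ZT6 than at ZT18 in limma's test (1235 and 1418 with cyclic loess), and in 3466 genes (50.6%, where chance gives 10%) the 3 values of one time all lay above the 3 of the other. The counts were 892 and 749 without replicate 3 and 919 and 942 without replicate 2, and 714 and 749 without ZT18 replicates 2 and 3, whose organelle signal was high. As lists with camera's preset correlation, photosystem subunits (adjusted p = 0.0031, median 0.92), photosynthesis genes (median 0.44) and plastid ribosomal proteins (adjusted p = 0.016, median 0.51) were higher and plastid-encoded genes lower (adjusted p = 0.0031; 0.341 in fry); adjusted p = 0.191, 0.689, 0.689 and 0.699 with an estimated correlation. In replicate 1 the plastid-encoded median level went the other way (8.31 at ZT6, 8.11 at ZT18), and it was lower at ZT6 in replicates 2 (9.76 against 11.27) and 3 (9.43 against 10.85). With cyclic loess the preset value was 0.0506 for plastid ribosomal proteins. Adjusted over the list alone, 5 photosystem genes, 10 photosynthesis genes and 6 plastid ribosomal protein genes were higher, 3 photosynthesis genes were lower, and 0 plastid-encoded genes passed, against 2 over all genes.

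At ZT12 against ZT0, the end of the afternoon against lights on, all 3 tested cold-regulated genes rose. COR15A was 5.48 ± 0.44 (log2, SD, n = 3) at ZT0 and 12.11 ± 0.55 at ZT12, a rise of 6.63 ± 0.30 (SE). COR15B rose by 6.57 ± 0.17 and COR47 by 2.55 ± 0.17. The starch breakdown genes DPE1 and PWD rose by 2.96 ± 0.17 and 2.04 ± 0.20, the 2 tested, and GI by 3.19 ± 0.20. AT4G30650 rose by 6.75 ± 0.20, AT1G56300 by 6.10 ± 0.16 and AT4G16146 by 5.51 ± 0.17. AT1G64500 fell by 5.73 ± 0.24, AT4G15430 by 5.66 ± 0.17, AT4G31875 by 5.56 ± 0.25, AT2G41250 by 5.13 ± 0.16 and AFR (AT2G24540), an F-box protein of far-red light signalling, by 4.83 ± 0.31. AKINBETA1, the 1 tested gene of the sugar starvation list, fell by 1.94 ± 0.21.

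Photosynthesis genes moved both ways between these times (4 rose, 5 fell, 10 of 19 did not pass; the same counts adjusted over the list alone). PORB rose by 1.71 ± 0.20, ATPC1 by 0.57 ± 0.17, PSBW by 0.48 ± 0.13 and LHCB4.1 by 0.33 ± 0.12 (adjusted p 0.042; 0.093 with median centring). RCA, which activates Rubisco, fell by 0.96 ± 0.25, CHLM by 0.82 ± 0.13, LHCB4.2 by 0.73 ± 0.15, AT1G80380 by 0.51 ± 0.18 and PSBY by 0.38 ± 0.13. Of the conserved-peptide genes 4 rose and 2 fell, with AT5G15950 at -2.16 ± 0.27, SAMDC at -1.61 ± 0.18, AT5G50010 at 1.60 ± 0.17 and AT1G73600 at 1.49 ± 0.19. PRL and HTB1, the 2 tested of the replication list, rose by 0.85 ± 0.20 and 0.74 ± 0.22. Of the plastid ribosomal proteins 3 of 10 rose, AT5G24490 by 0.70 ± 0.18, AT2G43030 by 0.50 ± 0.16 and AT4G17560 by 0.48 ± 0.17, and of the mitochondrial chain 2 of 9 fell, AT1G51980 by 0.71 ± 0.22 and AT5G47030 by 0.38 ± 0.14. AT5G37670 rose by 0.50 ± 0.18. Among 97 cytosolic ribosomal protein genes 2 rose and 4 fell in limma's test (0 adjusted over the list alone, 13 at an unadjusted p under 0.05). These included AT4G30800 at 0.72 ± 0.20, AT5G67510 at -0.53 ± 0.16, AT5G60670 at -0.48 ± 0.14 and AT1G48830 at 0.44 ± 0.14.

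In total 1257 genes were higher and 1261 lower at ZT12 than at ZT0 in limma's test, with 3260 genes (47.6%, where chance gives 10%) whose times did not overlap; without replicate 1 the counts were 774 and 849. Calls that ended without 1 of the ZT0 or ZT12 extracts, in at least 1 case, were those of ATPC1, PSBW, PSBY, LHCB4.1, HTB1, AT1G80380, AT2G43030, AT4G17560, AT1G51980, AT5G47030, AT5G37670, AT4G30800, AT5G67510, AT5G60670 and AT1G48830. Leaving out a whole replicate number ended those of LHCB4.2 (limma's adjusted p 0.0502 without replicate 1) and AT5G24490 (0.063 and 0.126 without replicates 1 and 2). That of RCA ended without replicate 3 (a change of -0.64, 0.109). Median centring also ended those of AT5G37670 and AT4G17560 (adjusted p 0.075 and 0.072 in limma), and cyclic loess those of AT5G37670 and AT5G47030 (0.062 and 0.055). With no filter on dim genes those of HTB1, AT5G37670, AT1G80380, AT1G51980 and AT4G17560 ended (0.062 to 0.103), with array weights that of AT1G80380 (0.052), with the replicate number as a block that of AT5G37670 (0.055), and with levels from summed values those of PSBY and AT1G48830 (0.096 and 0.068). None of the 8 lists tested with camera passed for this contrast (adjusted p 0.780 and above). Over the 4 times, 3978 genes differed in level in the F test, and these were highest at ZT0 in 1334 (33.5%), at ZT6 in 1087, at ZT18 in 820 and at ZT12 in 737. For genes with a group mean under 3, near the lower end of the scale (here GI, AT1G73480, AT1G13650, AT2G25990, AT4G12500, AT5G50010, AT4G15430 and AT4G31875), the size of a change is a difference from that lower end.

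**Figure D1:**
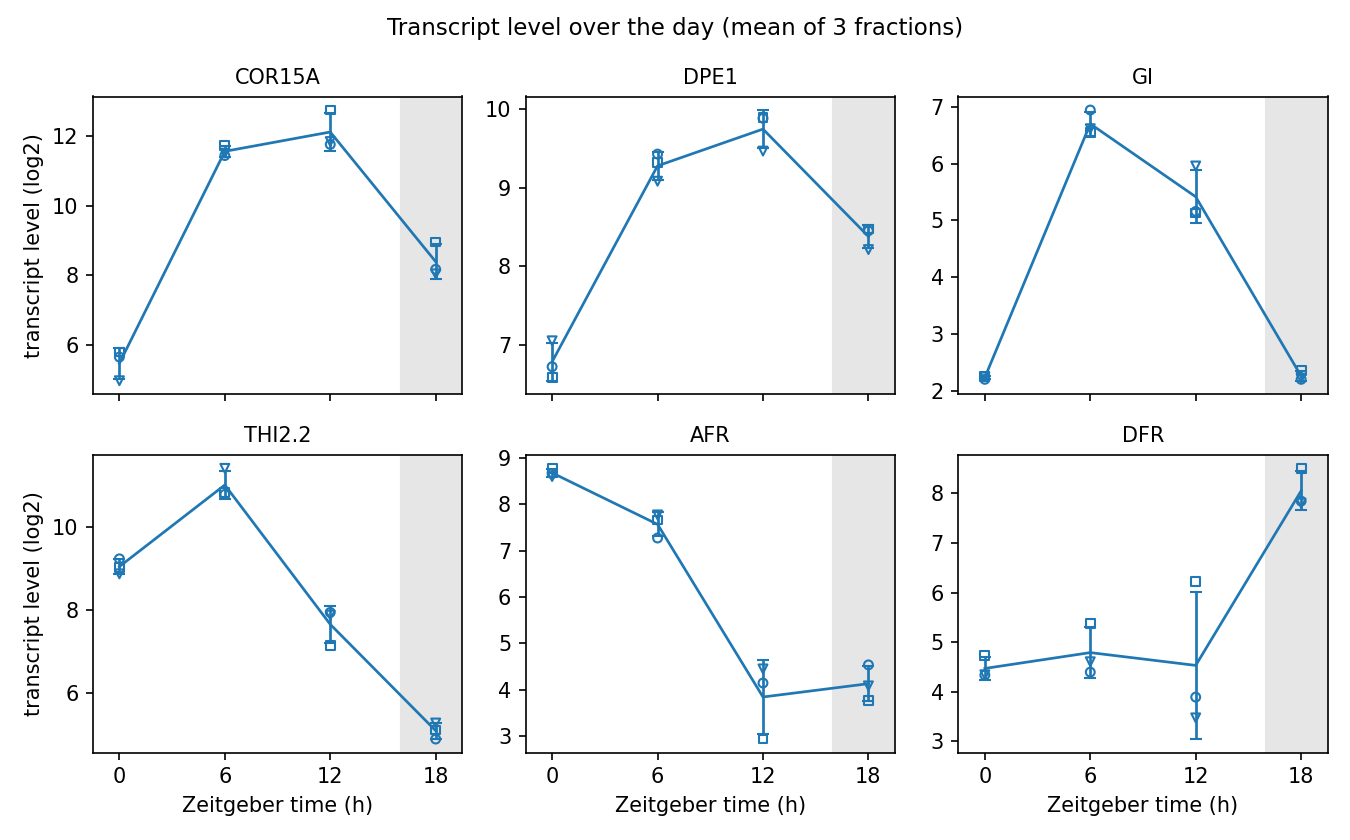
Transcript level (log2, mean of the 3 fractions of an extract) of 6 genes against Zeitgeber time in hours. Open symbols are the 3 replicates (circle, square and triangle for replicates 1, 2 and 3), lines join the means, bars are the SD, and grey marks the dark. COR15A rose from 5.48 at ZT0 to 12.11 at ZT12, and DFR was highest at ZT18, at 8.05.

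Ribosome loading over the day asked whether transcripts moved onto or off large polysomes between times. Loading of cytosolic ribosomal protein transcripts, as the list median, was lowest at ZT6 (-0.70 ± 0.20, SD, n = 3) and highest at ZT18 (-0.07 ± 0.06), with -0.26 ± 0.09 at ZT0 and -0.50 ± 0.26 at ZT12. Between ZT6 and ZT18 the difference was negative in 88 of 97 of these genes (median -0.52), and 10 passed the test (26 with the extract as a replicate block), each lower at ZT6. Among them were AT5G67510 at -2.25 ± 0.40 (SE), AT1G07070 at -1.69 ± 0.40, AT5G27850 at -1.36 ± 0.31 and AT3G60245 at -1.32 ± 0.28. Plastid-encoded transcripts went the other way: their median loading was -0.54 ± 0.16 at ZT6 and -2.22 ± 0.03 at ZT18, and the difference was positive in 62 of 62 genes (median 1.58). Of these, psbT, of photosystem II, passed on its own (2.61 ± 0.78, limma's adjusted p 0.047; 0.055 with cyclic loess), and 52 passed with the extract as a replicate block. The added polyadenylated control transcripts moved in the same direction as the plastid transcripts, at -1.17 ± 0.46 (SD, n = 3) at ZT6 and -2.32 ± 0.81 at ZT18.

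Among the genes called in the F test for loading over the 4 times, the largest range was that of AT2G47880, from -2.72 ± 0.30 (SD, n = 3) at ZT6 to 1.66 ± 0.51 at ZT18, a change of -4.38 ± 0.72 (SE) at ZT6 against ZT18. In the same set it was followed by AT4G29020 at -3.03 ± 0.63, AT2G43610 at -2.57 ± 0.49 and AT5G06270 at -2.36 ± 0.44. AT4G26600, also of this set, was lowest at ZT18 (-2.86 ± 0.68) and highest at ZT12 (-0.51 ± 0.56). Besides psbT, loading was higher at ZT6 than at ZT18 for AT1G01250 by 1.98 ± 0.53, AT5G64110 by 1.97 ± 0.31, AT1G70880 by 1.76 ± 0.49, AT5G44380 by 1.71 ± 0.50 and GI by 1.71 ± 0.35. Of these, AT2G47880, AT5G64110, AT1G70880 and GI had group means under 3, near the lower end of the scale. GI lay at that lower end at ZT18, so its loading there was not measured and its value is no measured change of loading. Among the mitochondrion-encoded genes 0 of 6 passed in limma's test (median 1.08, 0 at an unadjusted p under 0.05), with ccb452 at 1.54 ± 0.91 and cox1 at 1.24 ± 1.05. With the extract as a replicate block 3 did, among them these 2 (adjusted p 0.011 and 0.0038). The clock-linked gene AT5G52660 (0.73 ± 0.27) did not pass, and did with the extract as a replicate block (adjusted p 0.021). The other lists had 0 called members over all genes (adjusted over the list alone, PRL and CHLM passed), with PRL at 0.98 ± 0.36, COR47 at 0.80 ± 0.33, LHCB4.3 at -0.80 ± 0.41, CHLM at 0.75 ± 0.27, AT5G40810 at -0.89 ± 0.38, AT4G17560 at -0.85 ± 0.35 and AT3G25570 at -0.56 ± 0.46. PRL (adjusted p 0.0084), COR47 (0.045) and LHCB4.3 (0.049) passed with the block.

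In total 46 genes had higher and 299 lower loading at ZT6 than at ZT18 in limma's test. With the extract as a replicate block the counts were 301 and 680, and 345 genes were called in both fits. At an unadjusted p under 0.05 there were 1400, and in 2343 genes (34.2%, where chance gives 10%) the times did not overlap. The F test over the 4 times called 195 genes (770 with the extract as a replicate block), of which 126 (64.6%) had their highest loading at ZT18, 34 at ZT0, 23 (11.8%) at ZT6 and 12 at ZT12. With the block these were 412 (53.5%) at ZT18, 139 at ZT0, 170 (22.1%) at ZT6 and 49 at ZT12. With cyclic loess and no block they were 103 (58.2%) at ZT18, 25 at ZT0, 36 (20.3%) at ZT6 and 13 at ZT12. Adjusted over the list alone, 26 cytosolic ribosomal protein genes were lower, and 0 plastid-encoded genes passed, against 1 over all genes and 11 at an unadjusted p under 0.05 in limma. As lists, cytosolic ribosomal proteins and plastid-encoded genes passed camera with its preset correlation (both adjusted p = 5.3e-11). With an estimated correlation the adjusted p was 0.661 and 0.665, and with the extract as a replicate block too it was 0.299 and 0.039. In fry, without the block, ribosomal proteins passed (adjusted p 0.015) and plastid-encoded genes did not (0.417). In camera the mitochondrion-encoded list (adjusted p 0.089) passed with the block (7.1e-04), though not with the block and an estimated correlation (0.226). Leaving out 1 extract gave 6 to 60 higher and 72 to 358 lower calls. Higher and lower calls were 9 and 100 without ZT6 replicate 1, 6 and 72 without ZT6 replicate 3, 22 and 166 without ZT18 replicate 2 and 9 and 147 without ZT18 replicate 3. They were 4 and 50 without replicate 1, 12 and 94 without replicate 2, 0 and 0 without replicate 3, and 0 and 1 without ZT18 replicates 2 and 3. Without 1 of the ZT6 or ZT18 extracts the calls of psbT, AT1G01250, AT1G70880, AT5G44380, AT1G07070 and AT5G27850 ended in at least 1 case, and without ZT18 replicates 2 and 3 those of all genes named above for a loading change between ZT6 and ZT18 ended. That left 1 extract at ZT18, assumed to vary like the other groups, and the changes kept their direction. They were of similar size for AT2G47880 (-4.71), AT5G67510 (-2.25), AT5G06270 (-2.10) and psbT (2.26), and smaller for AT1G01250 (0.90), AT4G29020 (-2.19), AT1G70880 (1.29) and AT5G44380 (1.25). With no filter on dim genes the calls of psbT, AT1G01250, AT1G70880 and AT5G44380 ended (adjusted p 0.059 to 0.109 in limma), and with a trended robust variance that of psbT (0.072). With both polysomal fractions together those of psbT, AT1G01250, AT1G70880, AT5G44380, AT1G07070 and AT5G27850 ended (0.060 to 0.293). The F test called 122 genes without ZT0 replicate 1, 111 without ZT0 replicate 2, 51 without ZT6 replicate 1, 26 without ZT6 replicate 3, 112 without ZT18 replicate 2 and 91 without ZT18 replicate 3. It called 0, 0 and 1 without replicates 1, 2 and 3, and 7 without ZT18 replicates 2 and 3.

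**Figure D2:**
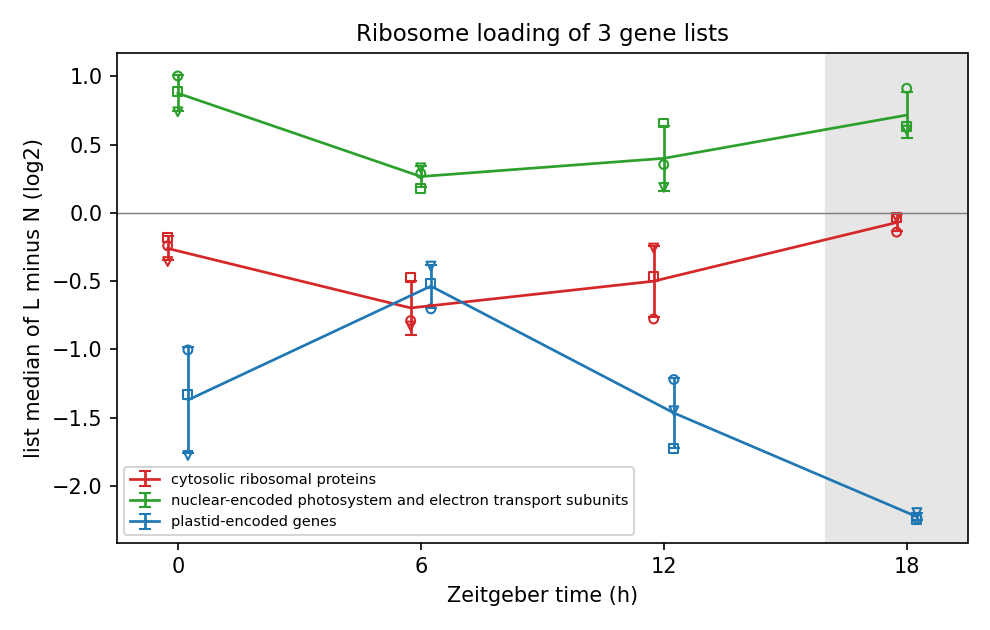
Loading (log2, large polysomal minus non-polysomal RNA, median of the list) of cytosolic ribosomal protein, nuclear photosystem and plastid-encoded genes against Zeitgeber time in hours. Open symbols are the 3 replicates (circle, square and triangle for 1, 2 and 3), lines join the means, bars are the SD, and grey marks the dark. At ZT18 the means were -0.07 for ribosomal proteins and -2.22 for plastid-encoded genes.

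At ZT12 against ZT0 the transcripts that changed loading were few. AT4G32340 had a loading of -2.32 ± 0.05 (SD, n = 3) at ZT0 and -0.17 ± 0.37 at ZT12, a change of 2.15 ± 0.40 (SE). AT3G53950 rose by 1.71 ± 0.32, AT3G03980 by 1.63 ± 0.31 and AT4G17100 by 1.53 ± 0.33. AT1G13920 went from 0.79 ± 0.43 to -1.41 ± 0.55, a change of -2.21 ± 0.42, and AT1G54410 changed by -1.38 ± 0.29. GI was called too, with a loading of 2.12 ± 0.55 at ZT12, but at ZT0 it lay at the lower end of the scale in both fractions and its loading there was not measured. Cytosolic ribosomal protein transcripts had a median change of -0.20, with 0 of 97 called in limma's test (5 at an unadjusted p under 0.05), and plastid-encoded transcripts of -0.02, with 0 of 62 (0 unadjusted).

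In total 8 genes were higher and 2 lower in limma's test (36 and 17 with the extract as a replicate block, 468 at an unadjusted p under 0.05), and in 997 genes (14.6%, where chance gives 10%) the times did not overlap. The higher and lower counts were 0 and 0 without ZT0 replicate 1, without ZT0 replicate 2 and without ZT12 replicate 1, 1 and 0 without ZT0 replicate 3, 8 and 5 without ZT12 replicate 2 and 7 and 1 without ZT18 replicate 3. They were 0 and 0 without replicate 1, 1 and 1 without replicate 2 and 1 and 0 without replicate 3. The call of AT4G17100 (limma's adjusted p 0.044) ended with median centring (0.051) and that of AT1G54410 (0.029) with cyclic loess (0.103), and each of the 7 named calls ended without at least 1 of the ZT0 and ZT12 extracts. With both polysomal fractions together those of AT3G03980, AT4G17100, AT1G13920 and AT1G54410 ended (0.076 to 0.080), and with every probe set tested that of AT4G17100 (0.063). The cytosolic ribosomal protein list passed camera with its preset correlation (adjusted p = 0.0039). The adjusted p was 0.850 with an estimated correlation, 0.069 with cyclic loess and 0.671 in fry.

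**Figure D3:**
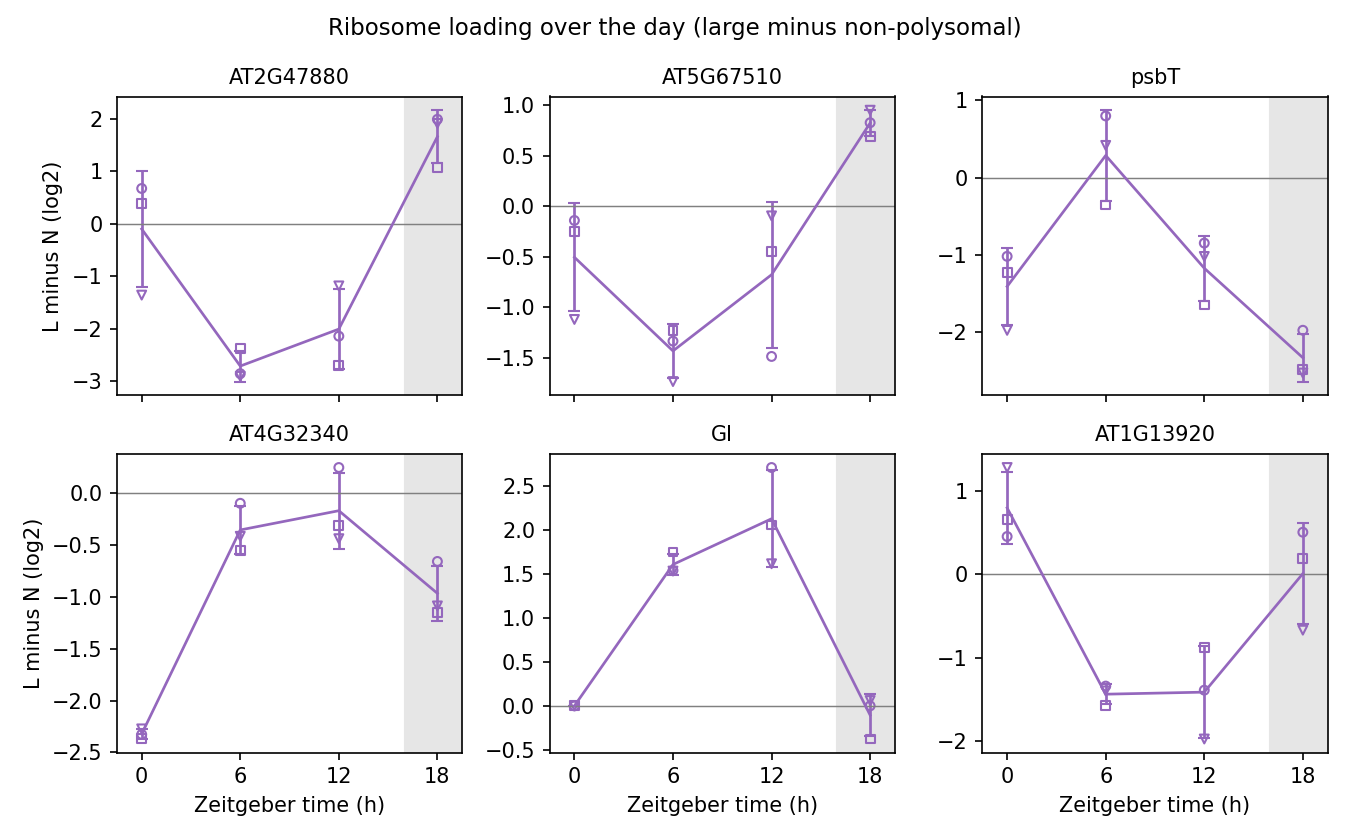
Loading (log2, large polysomal minus non-polysomal RNA) of 6 genes against Zeitgeber time in hours. Open symbols are the 3 replicates (circle, square and triangle for 1, 2 and 3), lines join the means, bars are the SD, and grey marks the dark. AT2G47880 went from -2.72 at ZT6 to 1.66 at ZT18, and psbT was lowest at ZT18. For GI the values at ZT0 and ZT18 lie at the lower end of the scale. AT2G47880 also had group means under 3, near that lower end.

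Whether loading and level changed in the same genes was asked by overlap. THI2.2 and AT2G47880 were among the 145 genes called in both F tests, and of the 5 genes with the largest loading range AT4G29020, AT4G26600 and AT5G06270 were too. AT2G43610 was not called for its level (adjusted p 0.083). GI was called in both too, but at ZT0 and ZT18 it lay at the lower end of the scale, where a change in level changes the loading value by itself. AT2G47880 also had group means under 3, near that lower end, so the same limit touches its joint call. The 145 compare with 113 for independent lists (odds ratio 2.13), and with the extract as a replicate block 483 compare with 447 (odds ratio 1.24). Loading and level come from the same arrays, and genes are not independent replicates, so that these are descriptions and the overlap was not tested against its own chance value. Of the 145, 6 had a group mean under 3, and among the 6728 genes with every group mean at least 3, 139 compare with 109 (odds ratio 2.07). Across genes the changes in level and in loading had a Pearson correlation of -0.08 (Spearman -0.08, covariance -0.0364 against -0.0109 by chance) for ZT6 against ZT18 and of 0.02 (Spearman -0.01, covariance 0.0061) for ZT12 against ZT0, with the same sign in 46.7% and 49.6% of genes. The count of 145 was 78 without ZT0 replicate 1, 76 without ZT0 replicate 2, 38 without ZT6 replicate 1, 20 without ZT6 replicate 3, 75 without ZT18 replicate 2 and 69 without ZT18 replicate 3. It was 0, 0 and 1 without replicates 1, 2 and 3, and 6 without ZT18 replicates 2 and 3.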

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

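Chosen after the result was seen were the test of the polyadenylated controls between ZT6 and ZT18, the test of ZT18 replicate 1, the shares of higher calls with the extract as a replicate block, and the counts without ZT18 replicates 2 and 3.

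Loading is a difference between fractions, and a difference of it between times drew attention: 195 genes in the F test, 46 higher and 299 lower at ZT6 than at ZT18, and 8 higher and 2 lower at ZT12 than at ZT0. The named genes are, for ZT6 against ZT18, psbT (2.61), AT1G01250 (1.98), AT5G64110 (1.97), AT1G70880 (1.76), AT5G44380 (1.71), AT2G47880 (-4.38), AT4G29020 (-3.03), AT2G43610 (-2.57), AT5G06270 (-2.36) and AT5G67510 (-2.25). For ZT12 against ZT0 they are AT4G32340 (2.15), GI (2.12, measured from the lower end of the scale at ZT0), AT3G53950 (1.71), AT3G03980 (1.63), AT4G17100 (1.53), AT1G13920 (-2.21) and AT1G54410 (-1.38). Probe sets that the text does not name, because the probe table pairs them with several genes or does not list them, also varied over the day: of 5853 bright enough, 137 differed in loading and 3583 in level.

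Plastid-encoded transcripts had a higher large minus non-polysomal difference at ZT6 than at ZT18 in 62 of 62 genes (median 1.58). An offset between arrays left in the deposited values did not account for it, since the median was 1.62 with median centring and 1.73 with cyclic loess. These moved the median change of all genes by only 0.039 and 0.035, so an effect of the authors' own normalization was not tested. For the high organelle signal of ZT18 replicates 2 and 3 there was 1 extract to compare. ZT18 replicate 1, with low signal, lay 1.53 below the lowest ZT6 value. On 1 extract this explanation is not excluded. Less polyadenylated mRNA per RNA in the non-polysomal fraction at ZT18 stays open and cannot be told apart from a change in loading, as the polyadenylated controls changed by 1.16 in the same direction, with 2 of 3 ZT6 extracts above every ZT18 extract. Within times the deviations of controls and plastid transcripts had a correlation of 0.62 over 12 extracts (permutation p 0.169), and time of day, a biological difference the design names, remains untested as its source.

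More genes had lower than higher loading at ZT6 against ZT18 (299 and 46). For these calls an offset between arrays left in the deposited values was argued against. The share of higher calls was at most 19.3% after subtracting the median of all genes, with median centring or with cyclic loess. That median was only -0.051, and median centring and cyclic loess moved it by 0.039 and 0.035. An effect of the authors' own normalization was therefore not tested. A single divergent extract was argued against as the source of this uneven balance. Leaving out each of the 6 extracts in turn gave a share of at most 16.5%. The number of calls did depend on single extracts and was lowest without ZT6 replicate 3 or ZT6 replicate 1. For the number, a divergent extract is not excluded. With ZT18 replicates 2 and 3 both left out the counts were 0 and 1, so the balance cannot be read there. With the extract as a replicate block the balance was less uneven (301 higher and 680 lower, a share of 30.7%). There the highest share was 38.9% with the same 3 corrections and 34.2% with 1 extract left out, so that an offset between arrays and a single divergent extract stay open for these calls. Time of day, which the design names, remains untested as the source.

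Cytosolic ribosomal protein transcripts had lower loading at ZT6 than at ZT18 (median -0.52). A change of all bright probe sets was argued against as the whole of it. The median lay at percentile 0 of 10000 lists matched on mean signal (their median -0.17, lowest -0.43). So was a change of all transcripts with low loading (percentile 0 of 10000 lists matched on mean loading, median -0.11, lowest -0.38). The medians of the matched lists were themselves below 0, so a part of the change was shared with such genes. An offset left in the deposited values was argued against too, with a median of -0.48 with median centring and -0.35 with cyclic loess. Both moved the median of all genes little (0.039 and 0.035), so an effect of the authors' own normalization was not tested here either. The matched lists were not drawn again with these scalings. A bias by transcript length, which was not tested here, stays open, and so does a shared swing of the list between extracts, given the adjusted p = 0.661 with an estimated correlation.

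Other splits of the arrays into groups of the same sizes, 100 each with the real one, gave fewer calls (the median of the others was 0 in each). A chance division of the samples was argued against for the counts of fractions and of level over the 4 times. For loading over the 4 times it was argued against with the extract as a replicate block. Large against non-polysomal RNA called 5323 genes and the other splits at most 4478 (4464 with labels exchanged within extracts), small polysomal against non-polysomal RNA 4294 and at most 2747 (2779), and large against small polysomes 4193 and at most 1258 (3578). The F test called 195 genes for loading and the others at most 0. Without the block the other splits mix times of differing level in a group. This widens the spread and lowers the loading calls by itself, so that count decides nothing. With the extract as a replicate block the F test called 770 genes for loading and the others at most 285. For level the F test called 3978 and the others at most 972. For both it called 145 and at most 0, which follows from the loading counts of 0 and tests nothing more. For the pairs of times the 10 splits are too few for a share under 0.05: loading called 345 genes at ZT6 against ZT18 (highest other 0) and 10 at ZT12 against ZT0 (highest other 1), and level 2596 and 2518 (highest other 0 for each). The real split was the 1 with as many calls in each of these comparisons.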

How the results depend on the processing

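Chosen after the data were seen were the counts without ZT18 replicates 2 and 3, those without organelle-encoded genes, the overlap without genes near the lower end of the scale and median centring for the list tests. No called list test or named gene change reversed its direction in any alternative run for it; which of the higher and lower counts was larger did turn with a scaling for the 3 comparisons of fractions and for level at ZT6 against ZT18. Of 172 named gene changes, 105 kept their call under each alternative and 67 lost it in at least 1. List tests lost their call in 17 cases and gained one in 15. These cases cover an estimated correlation, fry, no filter, cyclic loess and median centring, and leave out the replicate block. Counts below moved by over 1.5 times; the cause was not tested, except that more or fewer genes or arrays were tested where the filter, the probe sets or the extracts changed. With no filter, loading at ZT6 against ZT18 was higher in 75 genes, and at ZT12 against ZT0 higher in 29 and lower in 11; a mean of at least 6 gave 4 lower and a trended robust variance 7. With every probe set (12719), counts higher and lower were 5551 and 4391 for large against non-polysomal, 4405 and 3544 for small against non-polysomal, 4282 and 3548 for large against small, 115 and 486 for loading at ZT6 against ZT18, 2786 and 2289 for level at ZT6 against ZT18 and 2490 and 2421 at ZT12 against ZT0, with 327, 7589 and 251 called for loading, level and both over time. Array weights gave 130 and 479 for loading at ZT6 against ZT18, 13 and 8 at ZT12 against ZT0, 458 over time and 357 for both. The extract as a replicate block gave 301 and 680, 36 and 17, 770 and 483; with the replicate number too, 358 and 764, 41 and 24, and 866. The block changed no other count by over 1.5 times. Both polysomal fractions together against non-polysomal RNA gave 8 and 100, 3 and 1, and 44. Without ZT18 replicates 2 and 3, loading at ZT6 against ZT18 gave 0 and 1, over time 7, both 6, and level at ZT6 against ZT18 714 and 749.

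Leaving out 1 extract or 1 replicate number gave these ranges, where an arm with fewer samples is assumed to vary like the others: large against non-polysomal 2497 to 2730 higher and 2352 to 2587 lower, small against non-polysomal 1945 to 2259 and 1657 to 1988, large against small 1641 to 2057 and 1762 to 2147, loading at ZT6 against ZT18 0 to 60 and 0 to 358, loading at ZT12 against ZT0 0 to 10 and 0 to 5, level at ZT6 against ZT18 892 to 1495 and 749 to 1303, level at ZT12 against ZT0 774 to 1291 and 848 to 1290, loading over time 0 to 238, level over time 2662 to 4142, both 0 to 171, and the correlations -0.13 to -0.03 and -0.03 to 0.05. Replicate numbers across times were not taken as pairs, since 13 of 18 pairs of extracts with the same number correlated over 0.1, not all (-0.11 to 0.62); for replicate 1 each of 6 did (0.34 to 0.62), and its hybridisation controls in non-polysomal RNA (11.48 to 11.64) lay below those of the others (12.20 to 12.89) at each time, so a shared day or batch stays open. Of 12 extracts, 6 correlated best with their own number, and the replicate number as a block moved no level count by over 1.5 times. Genes near the lower end of the signal scale have compressed differences, and 6510 genes below a mean of 4 were not tested.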

Other observations

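The list counts of small polysomal RNA were chosen after the fits of the report were seen. Between small polysomal and non-polysomal RNA, plastid ribosomal protein transcripts were mostly lower in small polysomes (6 of 10 lower, 1 higher, median -0.41), and between large and small polysomes 7 were higher in the large and 2 lower (median 0.78). The 3 cold-regulated genes were all higher in large than in small polysomes (median 1.53), as were 3 of 4 chlorophyll synthesis genes, 3 of 3 proteasome genes, 5 of 9 mitochondrial chain genes and 5 of 5 photosystem genes (median 0.49). Mitochondrion-encoded transcripts were lower in small polysomal than in non-polysomal RNA in 4 of 6 (median -1.13), and lower in large than in small polysomes in 3 of 6. Of the light-harvesting genes 2 of 3 were lower in small polysomes and 0 higher.

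The 25S ribosomal RNA control probe set read 3.34 ± 0.85 (log2, SD, n = 12) in non-polysomal RNA and 2.22 ± 0.01 in small and in large polysomal RNA. The polysomal values lie at the lower end of the scale, so the amount of this RNA there was not measured. The polyadenylated controls read 6.23 ± 0.99 in non-polysomal, 5.72 ± 0.62 in small polysomal and 4.35 ± 0.38 in large polysomal RNA. The 3' minus 5' difference of the GAPDH probe sets was 6.89 ± 0.41, 7.83 ± 0.35 and 7.12 ± 0.58. For the actin probe sets it was 7.06 ± 0.56, 7.50 ± 0.47 and 7.98 ± 0.43. The 3' probe sets thus read far above the 5' ones in every fraction. Whether RNA quality or 3' bias affected the differences between fractions was not tested.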
